A study of Mus musculus with 4 samples.

How the data were processed

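Single cells from the lumbar spinal cord of C57BL/6 J mice were sequenced at 7 and 14 days after the left sciatic nerve was loosely ligated, a model of neuropathic pain. Each day gave 1 library from the injured (ipsilateral) side and 1 from the contralateral side, where the nerve was exposed without ligation. The deposited matrices hold counts of unique molecular identifiers (UMIs) for each gene and cell barcode, written by the authors with Cell Ranger 4.0.0 per the file headers, on the mm10 genome per the labels. All deposited barcodes had at least 500 UMIs. The number of animals per library, their sex, and whether both sides came from the same animals are not given in the sources used here. All 27998 listed genes were read; 27645 of their identifiers are in GENCODE M21, which gave the coordinates.

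Barcodes with at least 300 detected genes and at most 20% mitochondrial UMIs were kept. Doublets (barcodes holding more than 1 cell) were scored within each library with Scrublet in scanpy 1.11.5. Its automatic thresholds marked 0, 1, 0 and 422 barcodes in the day 7 ipsilateral, day 7 contralateral, day 14 ipsilateral and day 14 contralateral libraries. The highest scores were therefore removed at 0.8% per 1000 barcodes, a choice made after the data were examined. Of 43431 barcodes, 37160 remained.

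Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen across libraries. The scaled values gave 30 principal components (scikit-learn 1.9.0), from which a graph of 15 neighbours was clustered with leidenalg 0.10.2 at resolution 1, giving 43 clusters. Clusters were named from 141 markers of 19 cell types fixed before the data were examined. A name required at least 3 markers of the type at 2-fold or more over the median cluster, and no other type scoring within 1 log2 unit or holding more markers among the top 10 genes. The margin was added after the data were examined, because a mixed cluster of cells with few UMIs would otherwise have taken a name. Cells are called astrocyte-like, microglia-like and so on, since only RNA markers named them. Pericyte and smooth muscle markers were joined into a mural class.

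Raw counts were summed over the cells of a class in each library and divided by the class total, with all classes brought to the usual common total (CPM). Ratios are log2 of CPM with a pseudocount of 1 CPM, for genes with at least 100 counts over both libraries of the ratio. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals, and CPM values and their ratios carry exact Poisson or conditional binomial 95% intervals. These intervals cover counting error only. Each group is 1 library, so no test between groups was made, no p-value is given, and differences between animals or preparations cannot be estimated.

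The 24 gene lists were fixed before the data were examined. The myelin list and both homeostatic lists share many members with the markers that named the clusters, and the blood-brain barrier list shares some. A cluster low in those markers could go unnamed, which may limit the change these lists can show. A list is described by the median log2 ratio of its measured members and by the percentile of that median among 10000 random lists of the same size and matched mean expression. The percentile places a list among other genes of the same libraries and is not a test between groups. Lists with fewer than 3 measured members were not summarised. The genes named are members of these lists, and by a rule fixed at the same time the 10 highest and 10 lowest genes at least 1.25-fold apart in the same direction at both days, the 5 highest and lowest at each day, and the 10 highest and lowest for day 14 against day 7 in the same direction on both sides. These needed at least 0.2 of the CPM of the highest class, which limits RNA released from other cells. Mitochondrial, ribosomal protein, haemoglobin, sex-linked and unnamed genes were left out of that rule but not out of the lists. Clec7a, Ighm, Trac, Trbc2 and 9630013A20Rik are not in the files, and Itgam was left out because 2 identifiers carry it.

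Alternatives planned before the data were examined were a looser and a stricter cell filter (200 genes with no mitochondrial limit; 500 genes and 10%), doublets kept, resolutions 0.5 and 2, trimmed mean of M values (TMM) scaling (edgeR 4.0.16 in R 4.3.3), median-of-ratios scaling, cells weighted equally, a total without mitochondrial, ribosomal protein and haemoglobin genes and Malat1, cells thinned to 1000 UMIs, a pseudocount of 10 CPM, and count minimums of 20 and 1. Alternatives added later were equal cluster makeup, centring within 20 bins of gene length, and ratios relative to the other classes. Another was list members with at least 0.2 of the CPM of the highest class. Gene length is the genomic span from start to end, introns included. Ratios relative to the other classes subtract the median ratio in other classes and keep only genes also measured and expressed there. They rest on fewer genes, and their list medians can rest on fewer members. Equal cluster makeup used clusters with at least 20 cells in both libraries. Alternative list percentiles used 2000 random lists. Under the alternatives, the count minimum was checked for single genes only after centring within gene length and relative to the other classes.

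The computation was tested on simulated data with 200 altered genes per class and side comparison. The direction was right for all altered genes that passed the count minimum in 7 of 8 class comparisons, and for 192 of 193 in microglia-like cells at day 14. Across classes the 95% intervals covered the true ratio for 91.0% to 95.5% of altered genes. Counts were drawn as Poisson from the pooled profile of both libraries, which the intervals assume, so coverage near 95% follows from the setting. No shift between libraries, free RNA or difference in cell mix was simulated, so this checks the computation only. Tables were handled with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.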

Results

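The 4 libraries held 6093 barcodes and 29536567 UMIs (day 7 ipsilateral), 6240 and 28642023 (day 7 contralateral), 15630 and 91542571 (day 14 ipsilateral), and 15468 and 87667428 (day 14 contralateral). After filtering, 5311, 5532, 13308 and 13009 cells remained in that order. Median UMIs per barcode were 2278 and 2255 at day 7 and 4230.5 and 4166 at day 14. Cells in clusters that took no name made up 21.4% and 15.9% at day 7 and 12.2% and 11.4% at day 14, ipsilateral first, with median UMIs of 679, 796, 688 and 648. There was 1 library per group, so differences are given with counting intervals and were not tested.

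The first comparison asks how the cell makeup of the injured side differed from the other side. Microglia-like cells, the resident macrophages of the spinal cord, were 19.3% of ipsilateral and 13.5% of contralateral cells at day 7, a ratio of 1.43 (95% interval 1.30 to 1.57). At day 14 they were 32.8% and 22.7%, a ratio of 1.45 (1.38 to 1.52). Astrocyte-like cells, which clear potassium and glutamate around neurons, had the lower share on the ipsilateral side at both days: 6.40% against 9.16% at day 7 (ratio 0.699, 0.607 to 0.803) and 8.72% against 13.8% at day 14 (0.632, 0.586 to 0.680). T or NK cells were 0.734% against 0.470% at day 7 (ratio 1.56, 0.927 to 2.67) and 1.01% against 0.538% at day 14 (1.89, 1.40 to 2.55), but the stricter cell filter gave 0.530% against 0.549% at day 7. Oligodendrocyte-like cells, which make myelin, were 12.8% against 14.4% and 19.0% against 20.8%, and the day 7 ratio of 0.891 turned to 1.005 with the looser cell filter. Ependymal-like cells, which line the central canal, ran opposite ways, with ratios of 0.534 at day 7 and 1.24 at day 14. Endothelial-like cells had ratios of 0.954 (0.856 at resolution 0.5) and 0.672 (0.740 with doublets kept), and mural-like cells of the vessel wall 1.12 and 0.727. Shares sum to a whole within a library, so a higher microglia-like share lowers the others, and 1 library per side leaves differences in dissociation open.

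**Figure D1:**
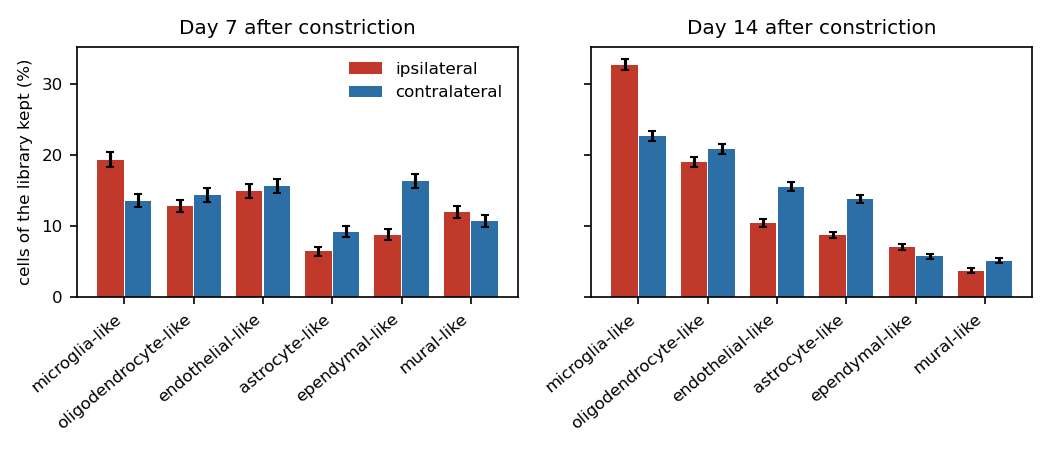
Bars give the percentage of kept cells in each of 6 classes for the ipsilateral and contralateral library at day 7 and day 14, with exact binomial 95% intervals as error bars. The microglia-like share was 19.3% against 13.5% at day 7 and 32.8% against 22.7% at day 14.

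The series title names MeCP2 and Kir4.1 in astrocytes, so the next comparison gives their genes in astrocyte-like cells. Kcnj10, which encodes the inward rectifier potassium channel Kir4.1 (ENSMUSG00000044708, chromosome 1, 172341210 to 172374085, plus strand, mm10), stood at 645 CPM (590 to 705) on the ipsilateral and 703 CPM (651 to 758) on the contralateral side at day 7, a ratio of 0.918 (0.816 to 1.03) that is within counting error of 1. At day 14 it stood at 643 CPM (613 to 673) and 774 CPM (751 to 798), a ratio of 0.830 (0.784 to 0.878) and a log2 ratio of -0.27. Kcnj16, whose product Kir5.1 joins Kir4.1 in mixed channels (ENSMUSG00000051497, chromosome 11, 110968033 to 111027968, plus strand), had ratios of 0.795 (0.596 to 1.05) and 0.712 (0.619 to 0.818). Mecp2, which encodes a protein that binds methylated DNA and recruits repressors (ENSMUSG00000031393, chromosome X, 74026592 to 74135363, minus strand), stood at 76.6 CPM (58.3 to 98.8) and 73.5 CPM (57.4 to 92.7) at day 7 and at 39.1 CPM (32.1 to 47.3) and 39.7 CPM (34.6 to 45.4) at day 14. Its ratios were 1.04 (0.725 to 1.49) and 0.986, with overlapping CPM intervals at both days, so a difference in Mecp2 between the sides was not detectable at this depth. Gfap, an intermediate filament gene of reactive astrocytes (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912, minus strand), had the higher level on the ipsilateral side, with ratios of 1.20 (1.03 to 1.40) and 1.47 (1.38 to 1.55).

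After thinning to 1000 UMIs per cell, Kcnj10 was detected in 43.5% and 44.3% of astrocyte-like cells at day 7 and in 39.7% and 49.1% at day 14, ipsilateral first, and in 4.55%, 4.11%, 2.45% and 4.99% of microglia-like cells, which should lack it. In oligodendrocyte-like cells the shares were 30.1%, 27.0%, 19.4% and 23.8%. At day 14 endothelial-like (2.53% against 3.51%), ependymal-like (14.1% against 14.9%) and mural-like cells (4.35% against 5.52%) were also lower ipsilaterally, with overlapping intervals. The lower Kcnj10 share at day 14 was therefore not particular to astrocyte-like cells. The Kcnj10 log2 ratio in thinned astrocyte-like cells was 0.021 at day 7, the other direction, and -0.50 at day 14. Thinned shares for Mecp2 in astrocyte-like cells were 6.94%, 9.22%, 3.78% and 3.36%. Median UMIs before thinning were 1273.5, 1069, 1118 and 1731 in astrocyte-like and 2789, 2648, 6177 and 5650 in microglia-like cells, and thinning left out 124, 225, 499 and 428 astrocyte-like cells with fewer UMIs.

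**Figure D2:**
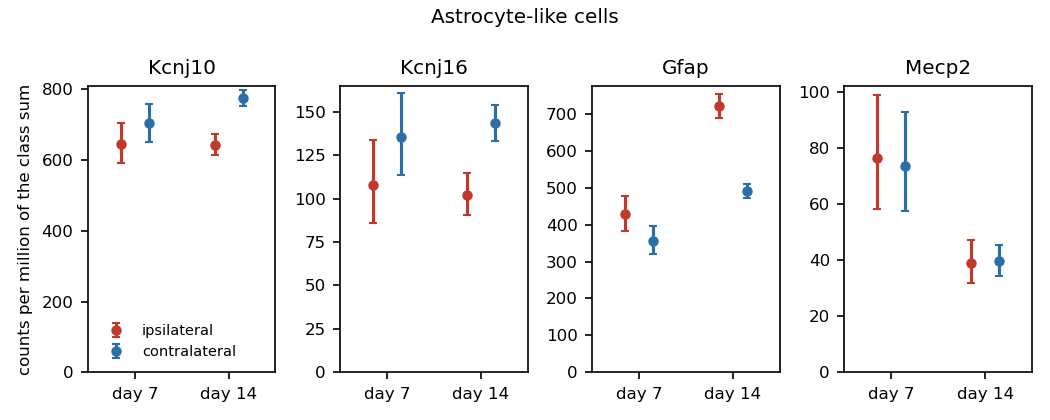
Points give CPM of Kcnj10, Kcnj16, Gfap and Mecp2 summed over astrocyte-like cells for each side and day, with exact Poisson 95% intervals. Kcnj10 stood at 643 CPM ipsilaterally and 774 CPM contralaterally at day 14, and Gfap at 721 and 492 CPM.

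Genes of astrocyte support functions were lower on the injured side at day 14. Of 17 genes for potassium, glutamate and water handling and gap junctions, 14 were lower and 3 higher, with a median log2 ratio of -0.23 (percentile 0). Examples were the GABA transporter gene Slc6a11 at -0.46, the sodium pump gene Atp1a2 at -0.35, the gap junction gene Gja1 at -0.29 and the glutamate transporter gene Slc1a2 at -0.23. Several members, among them Slc6a11, Gja1 and Slc1a2, were also markers that named the class. At day 7 the same list had 9 members higher and 8 lower, with a median of 0.02 (percentile 94.9). Centring within gene length gave medians of -0.13 at both days, which turns the day 7 direction, and thinned cells gave -0.14 at day 14. Shares of thinned cells with a UMI of Slc1a2 were also lower ipsilaterally at day 14 in classes that should lack it, at 5.86% against 10.0% in microglia-like and 5.05% against 9.28% in endothelial-like cells. Astrocyte-like cells also differed at day 14 in mitochondrially encoded (-0.28) and immediate early genes (0.54). Free RNA and a difference between the libraries therefore stay open as contributions to the lower support genes. The potassium channel list had medians of -0.12 (5 measured) and -0.17 (8 measured). Of the 14 pan-reactive genes only 5 had enough counts: their median was -0.37 (percentile 4.7) at day 7 and 0.34 (percentile 97.4) at day 14, with 5 of 5 higher at day 14. The day 7 value turned to 0.12 and 0.27 with count minimums of 20 and 1, and the day 14 value was 0.12 to 0.16 for members well expressed in the class, with equal cluster makeup and with the looser cell filter. Stat3, the transcription factor of the cytokine response, stood at 93.5 CPM (73.2 to 118) against 38.3 CPM (27.0 to 52.8) at day 7, with a log2 ratio of 1.27, and had 0.12 at day 14. Genes higher at both days were Fndc4 (0.57 and 0.52), the phospholipid enzyme gene Pcyt2 (0.46 and 0.49) and the collagen gene Col11a2 (0.66 and 0.34). Genes lower at both days included Amer2, a regulator of Wnt signalling (-0.63 and -0.41), Zhx3 (-0.37 and -0.60) and Por, the electron donor of cytochrome P450 enzymes (-0.33 and -0.43).

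The list of MeCP2 and partner repressors had a median of 0.22 at day 7 (6 measured, percentile 86.9) and -0.05 at day 14 (12 measured, percentile 44.7) in astrocyte-like cells. Cholesterol synthesis genes had medians of -0.17 and -0.09. Several immune lists had positive medians: cytokines 0.47 and 0.70, MHC class I 0.21 and 0.41, and complement 0.37 and 1.30. At day 14 A1-type genes had 0.93 and interferon genes 0.38. No day 7 median is given for the A1-type and interferon lists, so nothing is said of their direction then. The A1-type median turned to -0.067 with a count minimum of 1. A2-type genes had -0.03 and 0.45. Ccl5, a chemokine gene, stood at 26.3 CPM against 8.53 CPM at day 14. Most members of these lists had under 0.2 of the CPM of the highest class, which leaves RNA from those cells within the astrocyte-like droplets as an open contribution. The immediate early list, a sign of handling stress, had medians of 0.24 and 0.54, and heat shock genes had -0.44 and 0.18.

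In microglia-like cells, interferon-induced genes, which answer antiviral and tissue-damage signals, were higher on the injured side. All 14 members were higher at day 7 with a median log2 ratio of 0.74 (percentile 100), and 13 of 14 at day 14 with a median of 0.44 (percentile 100). The antiviral gene Rsad2 stood at 22.6 CPM (19.0 to 26.8) against 3.70 CPM (1.97 to 6.33) at day 7 and at 4.76 CPM against 2.64 CPM at day 14. Ifit3 had log2 ratios of 1.40 and 0.60, Irf7, which encodes a transcription factor of the interferon response, 0.89 and 0.68, and Isg15 0.75 and -0.26 (0.24 relative to other classes). In endothelial-like cells the same list had medians of -0.11 and 0.11. In cells thinned to 1000 UMIs the microglial median was 0.02 over the 3 members left at day 7 and 0.16 over the 10 left at day 14. Without cells that held a UMI of a blood or border immune marker it was 0.65 at day 7 and 0.13 at day 14, with 8 of 12 members higher at day 14. The 5 members with at least 0.2 of the CPM of the highest class had medians of 0.58 and 0.45. A pseudocount of 10 CPM gave 0.48 and 0.28. The day 7 median relative to other classes was 0.46, over only those members also expressed in other classes.

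**Figure D3:**
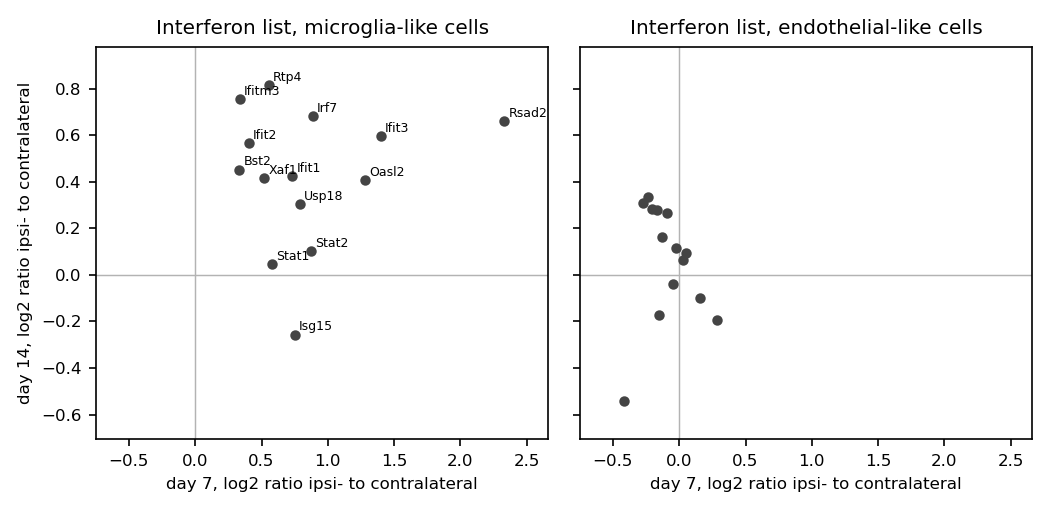
Each point is an interferon-induced gene, with its log2 ratio of ipsilateral to contralateral CPM at day 7 on the x axis and at day 14 on the y axis, in microglia-like cells (left, named) and endothelial-like cells (right). The medians were 0.74 and 0.44 in microglia-like and -0.11 and 0.11 in endothelial-like cells.

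Other microglial genes were higher ipsilaterally at both days. Ccl12, a monocyte-attracting chemokine gene, stood at 414 CPM (398 to 430) against 220 CPM (205 to 236) at day 7 and at 728 CPM (718 to 738) against 369 CPM (359 to 378) at day 14. Its relative Ccl2 had log2 ratios of 0.77 and 0.83. The lipid carrier gene Apoe had 1.16 and 0.50, the complement gene C4b 1.80 and 2.42, the nucleic acid sensor gene Zbp1 0.98 and 1.12, the protease inhibitor gene Cst7 0.82 and 0.83, and the Fc receptor gene Fcgr4 0.60 and 0.70. The CPM of Rsad2, Irf7, Ccl2, Apoe and C4b in microglia-like cells was 0.059, 0.138, 0.091, 0.136 and 0.138 of that in the highest class, so RNA from other cells stays open for them. The disease-associated list had 11 of 16 members higher at day 7 (median 0.14, percentile 91.7) and 15 of 18 at day 14 (median 0.29, percentile 100). Its day 7 median was 0.03 with cells weighted equally and -0.09 in thinned cells and 0.47 relative to other classes, and its day 14 median was 0.08 with equal cluster makeup. Homeostatic genes, many of which also named the class, had medians of -0.07 and -0.21 (percentile 1.34). Among them were the purine receptor gene P2ry12 at -0.50 and -0.33 and the lipid receptor gene Gpr34 at -0.55 and -0.24. TMM and median-of-ratios scaling moved the median of all genes at day 14 by 0.18 and 0.17. The homeostatic median was then -0.01 and -0.03, the disease-associated median 0.48 and 0.47 and the interferon median 0.63 and 0.62, and the homeostatic median was -0.02 after centring within gene length. Lower at both days were the adaptor gene Bank1 (-0.72 and -0.72), the transcription factor gene Sox4 (-0.61 and -0.56) and Upk1b (-0.81 and -0.50). In thinned cells, where the count minimum was not applied to single genes, Bank1 turned to 0.04 at the day nearer to 0.

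Genes linked to microglial pain signalling had medians of 0.03 and 0.11, with the purine receptor gene P2rx4 at 0.35 and -0.02 and the transcription factor gene Irf8 at 0.03 and -0.04. Cytokines and chemokines had medians of 0.10 and 0.13, with Il1b at 0.09 and 0.32 and Tnf at -0.28 and 0.05. With equal cluster makeup the day 14 median turned to -0.06 and Tnf to -0.099, and Tnf turned to -0.028 after centring within gene length. MHC class I genes, which present antigen, had 0.11 and 0.29, MHC class II genes -0.33 and 0.41, and complement genes -0.16 and 0.42. Proliferation genes had -0.17 (4 measured) and -0.02 (9 measured). MeCP2 and partner repressors had 0.31 (percentile 98.8) and -0.26 (percentile 17.9), immediate early genes -0.12 and -0.07, and heat shock genes -0.10 and -0.07.

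In oligodendrocyte-like cells, myelin genes had -0.11 (percentile 7.04) at day 7 and 0.03 (percentile 12.2) at day 14. The main myelin protein gene Plp1 had 0.30 and -0.16 and Mbp -0.14 and 0.00. Many myelin genes, Plp1 and Mbp among them, also named the class, which may limit the change this list can show. TMM and median-of-ratios scaling gave myelin medians of -0.21 and -0.23 at day 7, where the median of all genes moved by -0.09 and -0.11, and equal cluster makeup gave -0.20. Cholesterol synthesis genes had 0.00 and 0.04, MHC class I genes 0.33 and 0.11, immediate early genes -0.12 (0.18 with cells weighted equally and 0.032 in thinned cells) and 0.23, heat shock genes -0.04 and 0.02, and MeCP2 and partner repressors 0.17 and -0.08. The extracellular matrix gene Tnr stood at 3.4 CPM (2.18 to 5.06) against 13.3 CPM (10.8 to 16.3) at day 7 and at 12.7 CPM (11.4 to 14.1) against 18.2 CPM (16.7 to 19.8) at day 14. Serpina3n, a protease inhibitor gene of reactive glia, had log2 ratios of 0.39 and 0.41. In thinned cells the day 14 log2 ratios turned to 0.18 for Tnr and -0.31 for Serpina3n, and Tnr turned to 0.29 with cells weighted equally. The count minimum was not applied to these thinned values.

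In endothelial-like cells, blood-brain barrier genes ran opposite ways, with a median of 0.13 at day 7 (9 of 12 higher, percentile 97.6) and -0.21 at day 14 (10 of 12 lower, percentile 0.66). The drug efflux gene Abcb1a had 0.40 and -0.54 and the amino acid transporter gene Slc7a5 0.20 and -1.26. After centring within gene length these medians were 0.01 and -0.01. Activation genes, which mark inflamed vessels, had medians of 0.28 (percentile 99.3) and 0.14 (percentile 95.9), with the adhesion molecule gene Vcam1 at 0.28 and 0.21. The day 7 activation median turned to -0.18 in thinned cells and -0.025 with equal cluster makeup. Vcam1 turned to -0.025 at day 7 with equal cluster makeup and to -0.32 at day 14 in thinned cells, there without the count minimum. Isg15 stood at 289 CPM (276 to 303) against 386 CPM (371 to 401) at day 7 and at 262 CPM (251 to 274) against 382 CPM (372 to 393) at day 14. The oxidase gene Cyp2e1 had -0.50 and -1.64. MHC class I genes had -0.03 and 0.13, immediate early genes -0.08 and -0.09 (day 14 turned to 0.003 with median-of-ratios scaling and 0.005 relative to other classes), heat shock genes -0.17 and -0.05, and MeCP2 and partner repressors 0.13 and -0.23.

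Lists that follow RNA quality and blood also differed between the sides. Mitochondrially encoded genes were higher ipsilaterally at day 7 and lower at day 14, with medians of 0.19 and -0.28 in astrocyte-like, 0.42 and -0.36 in microglia-like, 0.11 and -0.49 in oligodendrocyte-like and 0.38 and -0.48 in endothelial-like cells. Relative to other classes they turned to -0.031 and 0.17 in astrocyte-like and, at day 14, to 0.071 in microglia-like cells. Haemoglobin genes had medians of 2.47 and 2.44 in endothelial-like cells, where the day 14 value turned to -1.93 with doublets kept, and at day 14 of 0.32 in astrocyte-like, -0.28 in microglia-like and 2.52 in oligodendrocyte-like cells. The sex-linked list had medians of 0.29 and -0.45 in microglia-like, 0.33 and -0.08 in oligodendrocyte-like, 0.22 and -0.18 in endothelial-like cells and -0.28 at day 14 in astrocyte-like cells. This list joins Xist with the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, so its median cannot show a difference in the sex of the animals.

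The only repeat of the side comparison in the design is the other day, so the ratios of all genes were set against each other. Across genes within a class, which are not independent replicates, the day 7 and day 14 log2 ratios had Pearson r of -0.40 (astrocyte-like), -0.37 (microglia-like), -0.34 (oligodendrocyte-like) and -0.34 (endothelial-like), with Spearman rho of -0.49, -0.45, -0.47 and -0.51. The same direction at both days was found for 29.2% of 2967, 30.7% of 7699, 29.9% of 8856 and 27.7% of 9008 genes. Relative to the ratio of the same gene in other classes, these shares were 41.0% of 2320, 50.4% of 6108, 52.7% of 6520 and 50.8% of 6801 genes. Genes with a longer genomic span, introns included, had the higher ratios at day 7 and the lower at day 14. Spearman rho between this length and the ratio was 0.38 and -0.42 in astrocyte-like and 0.37 and -0.43 in microglia-like cells. Most genes therefore did not repeat their direction, and a gene seen at a single day rests on 1 library per side.

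**Figure D4:**
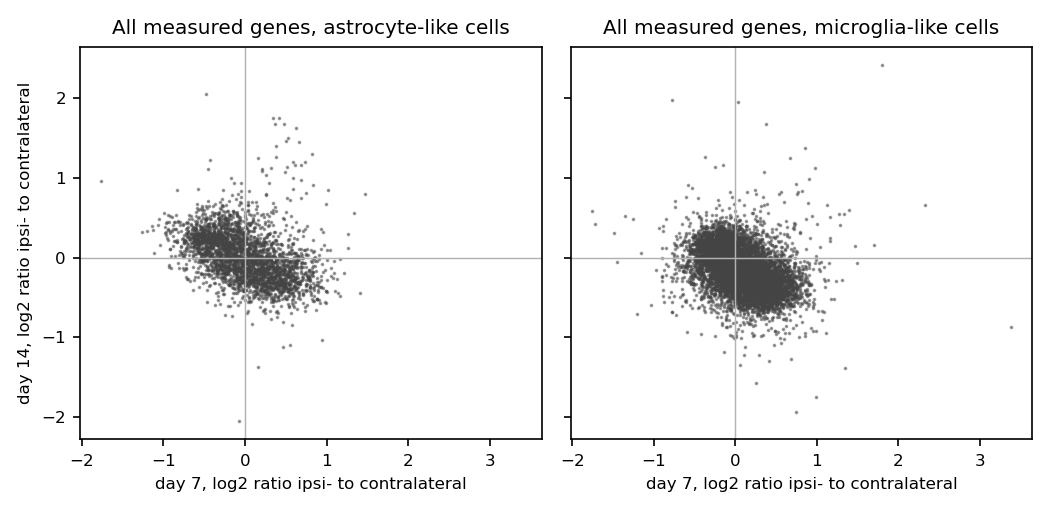
Each point is a gene with at least 100 counts in both ratios, with its log2 ratio of ipsilateral to contralateral CPM at day 7 on the x axis and at day 14 on the y axis. Pearson r was -0.40 in astrocyte-like and -0.37 in microglia-like cells.

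The last comparison sets day 14 against day 7 on each side. Each day is its own pair of libraries with different depth, so day and library batch cannot be told apart. In endothelial-like cells, activation genes were lower at day 14 with medians of -1.98 ipsilaterally (7 of 7 lower) and -1.97 contralaterally (6 of 7 lower). Lcn2, which encodes an acute-phase iron-binding protein, stood at 15.1 CPM (12.6 to 18.0) at day 14 against 1584 CPM (1553 to 1616) at day 7 ipsilaterally, and at 8.56 CPM (7.02 to 10.3) against 1682 CPM (1651 to 1713) contralaterally. The chemokine scavenger gene Ackr1 had log2 ratios of -3.94 and -4.65, Lrg1 -3.72 and -5.20 and the prostaglandin synthase gene Ptgs2 -3.12 and -2.84. Cluster 15 held 43.0% and 50.7% of endothelial-like cells at day 7 and 0.793% and 1.19% at day 14, while cluster 4 held 8.20% and 9.47% and then 71.7% and 68.5%. With equal cluster makeup, which drops clusters with few cells at a day, the activation medians were -0.78 ipsilaterally and 0.52 contralaterally, so the contralateral direction turned. Single genes turned too, with Ackr1 at 0.86 and 2.79 and, contralaterally, Lrg1 at 1.10 and Ptgs2 at 0.59. Under this setting cluster 15 was dropped ipsilaterally, with 11 cells at day 14. Contralaterally it was kept, with 24 cells at day 14 against 439 at day 7. The values of the 2 sides under equal cluster makeup thus rest on different clusters and are not comparable. Members well expressed in the class had medians of -2.85 and -3.31.

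In oligodendrocyte-like cells, Sgk1, a kinase gene induced by glucocorticoids, was among the genes lower at day 14 on both sides. It stood at 138 CPM (134 to 142) against 878 CPM (856 to 900) ipsilaterally and at 131 CPM (127 to 135) against 1165 CPM (1140 to 1191) contralaterally. The lipid droplet gene Plin4 had log2 ratios of -5.69 and -5.87, the transcription factor gene Klf15 -2.32 and -2.70 and Zbtb16 -2.80 and -2.30. Cholesterol synthesis genes were higher, with medians of 0.81 and 0.61 (12 of 14 higher on both sides), among them Hmgcs1 at 0.80 and 1.21. TMM moved the median of all genes by 0.24 and 0.13 and the cholesterol medians to 1.07 and 0.74. Cluster 3 held 64.0% and 70.6% of oligodendrocyte-like cells at day 7 and 29.4% and 29.2% at day 14, while cluster 2 rose to 44.6% and 50.5% at day 14. With equal cluster makeup the cholesterol medians were both 0.48, and Sgk1, Plin4, Klf15, Zbtb16 and Hmgcs1 kept their directions with ratios nearer to 1.

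In astrocyte-like cells the Notch target gene Hes5 (1.57 and 1.39), the fatty acid binding protein gene Fabp7 (1.71 and 1.17) and Id3 (1.38 and 1.0) were higher at day 14, and Etnppl (-2.56 and -1.67), Hr (-3.15 and -2.20) and the clock gene Per1 (-1.47 and -1.10) were lower, ipsilateral first. Relative to other classes Per1 turned to 0.087 and 0.18, so its fall was not particular to astrocyte-like cells. In microglia-like cells the galectin gene Lgals3 (2.69 and 2.42) and the lipase gene Lpl (2.01 and 1.92) were higher and the receptor gene Cd300lf (-3.63 and -4.0) was lower. The disease-associated list had medians of 0.49 and 0.31 and the interferon list -0.80 and -0.27. Cluster 14 held 52.4% and 38.1% of microglia-like cells at day 7 and 0.573% and 0.644% at day 14, while cluster 0 held 2.24% and 3.34% and then 50.2% and 56.2%. With equal cluster makeup the disease-associated medians turned to -0.15 and -0.081, and contralaterally the interferon median turned to 0.59 and Lpl to -0.76. The direction of these values therefore depends on which clusters are compared, while Lgals3, Cd300lf, ipsilateral Lpl and the ipsilateral interferon median kept theirs. Relative to other classes the ipsilateral disease-associated median was -0.087. Immediate early genes were lower at day 14 in astrocyte-like (-0.43 and -0.79), oligodendrocyte-like (-0.74 and -1.11) and endothelial-like cells (-0.88 and -0.70) and higher in microglia-like cells (0.39 and 0.20). With equal cluster makeup they turned to 0.11 ipsilaterally in astrocyte-like and -0.27 contralaterally in microglia-like cells, and relative to other classes to 0.12 ipsilaterally in astrocyte-like cells. MHC class I genes had medians of -0.82 and -0.77 in microglia-like and -0.73 and -0.78 in endothelial-like cells. TMM moved the median of all genes on the ipsilateral side by 0.19 in astrocyte-like, 0.22 in microglia-like and 0.13 in endothelial-like cells.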

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

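The tests on gene length, on a difference shared by all classes and on swapped sides were chosen only after the result they examine had been seen. Some list medians lay outside 95% of matched random lists in opposite directions at day 7 and day 14, and these differences between days were not tested. The day 14 minus day 7 difference of the log2 medians was 0.74 for MHC class II in microglia-like cells (-0.33, then 0.41) and -0.34 for blood-brain barrier genes in endothelial-like cells (0.13, then -0.21). After centring within gene length the blood-brain barrier medians were 0.013 at day 7 and -0.005 at day 14. The difference was 0.36 for immediate early genes in oligodendrocyte-like cells (-0.12, then 0.23), but the day 7 value was 0.18 with cells weighted equally and 0.032 in thinned cells. Mitochondrially encoded genes differed by -0.48 in astrocyte-like, -0.78 in microglia-like and -0.85 in endothelial-like cells, and relative to other classes their medians turned at both days in astrocyte-like (-0.031, then 0.17) and at day 14 in microglia-like cells (0.071).

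The wider pattern is that side ratios of all genes ran opposite ways at the days, with a median between-day r of -0.34 over 6 classes. Gene length as the whole cause was argued against, since r was still -0.24 after centring within length bins. Swapped sides at a day were argued against because the smaller microglia-like share ratio of both days was 1.43, on the same side at both. A difference between libraries that all classes share remains a candidate explanation: ratios of different classes correlated within a day (median r 0.54 and 0.67), and r was -0.01 relative to other classes. That last value rests on fewer genes. A response of the whole tissue that differs between the days would look the same and stays open, untested with 1 library per group.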

How the results depend on the processing

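Equal cluster makeup, gene-length centring, ratios relative to other classes and the restriction to members well expressed in the class were chosen only after the data were seen. Of 487 alternative values of the main results, 401 stayed within their spread, 81 moved beyond it and 5 turned direction. A turn was counted only where the first value lay beyond counting error or matched lists, and 27 of the 487 changed sign in all. For 20 microglial genes apart at both days the counts were 259, 45 and 3 of 307, for the other named genes 1643, 400 and 21 of 2064, and for the other lists 1285, 259 and 19 of 1563. At resolution 0.5 the endothelial-like share ratio at day 7 was 0.856, and no other main result moved at resolutions 0.5 and 2. Causes were not tested unless stated. No paired analysis was possible because the labels do not pair the sides by animal, and leaving out a library was not possible with 1 per group. Values below are log2 medians unless given as a percent or share ratio, and a percent is the share of genes with the same direction at both days. Depth limited most of all the astrocyte-like class at day 7, with 2969 genes over the count minimum against 8113 at day 14.

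The looser cell filter gave a microglia-like share ratio of 1.28 at day 7, an oligodendrocyte-like share ratio that turned to 1.005 at day 7, a pan-reactive median of 0.16 at day 14, and 28.3% (oligodendrocyte-like) and 26.5% (endothelial-like). The stricter filter gave a share ratio of 1.30 at day 7, and 24.0% (astrocyte-like), 32.0% (microglia-like) and 28.6% (oligodendrocyte-like), and turned Slc6a11 in astrocyte-like cells to -0.022 at day 7. It also gave a ratio of 0.966 for T or NK cells at day 7, within the wide interval of that ratio. Doublets kept gave an endothelial-like share ratio of 0.740 at day 14 and 26.5% (endothelial-like), and turned haemoglobin genes in endothelial-like cells to -1.93 at day 14. The reduced total gave 29.6% (microglia-like) and 28.7% (oligodendrocyte-like).

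TMM gave, at day 14 in microglia-like cells, -0.013 (homeostatic), 0.48 (disease-associated) and 0.63 (interferon), then -0.21 for myelin at day 7, and 1.07 and 0.74 for cholesterol synthesis, day 14 to day 7, ipsilateral and contralateral. Median-of-ratios scaling gave -0.025, 0.47, 0.62 and -0.23 for the first 4 of these and 1.07 for cholesterol synthesis ipsilaterally. Both scalings moved the median of all genes, which accounts for moves of that size. Cells weighted equally gave 0.033 (disease-associated) and 0.61 (interferon) at day 7, and 38.3% (astrocyte-like), 37.5% (oligodendrocyte-like) and 31.4% (endothelial-like). In oligodendrocyte-like cells they turned Tnr to 0.29 at day 14 and immediate early genes to 0.18 at day 7, and median-of-ratios scaling turned endothelial immediate early genes to 0.003 at day 14.

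Thinned cells gave -0.50 for Kcnj10 and -0.14 for homeostatic genes in astrocyte-like cells at day 14. In microglia-like cells they gave -0.089 (disease-associated, day 7), 0.015 and 0.16 (interferon, day 7 and 14, where fewer members had enough counts). Endothelial activation, day 14 to day 7, was -1.66 and -1.73. The percents were 37.5, 28.7, 35.8 and 29.3 in astrocyte-like, microglia-like, oligodendrocyte-like and endothelial-like cells. The smaller log2 ratio of both days turned to 0.04 for Bank1, 0.48 for Efnb1 and 0.042 for Tal1 in microglia-like cells, all lower otherwise. Between the sides, thinning also turned Tnr to 0.18, Serpina3n to -0.31, Vcam1 to -0.32 (endothelial-like) and Csrp1 to -0.022 (mural-like) at day 14. At day 7 it turned B4galt3 to -0.72 (ependymal-like), endothelial activation to -0.18 and immediate early genes to 0.032 (oligodendrocyte-like). The thinned values of single genes had no count minimum and carry no interval, so their turns may rest on few counts.

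A pseudocount of 10 gave 0.48 and 0.28 for interferon in microglia-like cells at day 7 and 14, and -1.76 for endothelial activation contralaterally; a larger pseudocount draws ratios of genes with few counts toward 0 by construction. A count minimum of 20 gave 0.12 for pan-reactive genes at day 7 and 37.9%, 33.8%, 33.9% and 32.1% in the class order above. A minimum of 1 gave 0.27, 42.1%, 38.3%, 38.4% and 36.9%, and -1.60 and -1.82 for endothelial activation, and turned A1-type genes in astrocyte-like cells to -0.067 at day 14; these minimums add genes with more counting noise.

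Equal cluster makeup gave 0.14 (pan-reactive) and 0.077 (disease-associated) at day 14 and -0.20 (myelin) at day 7. Day 14 to day 7 it gave 0.48 for cholesterol synthesis ipsilaterally, -0.78 for endothelial activation ipsilaterally and 0.52 contralaterally, where the direction turned. The percents were 34.8 (astrocyte-like), 39.1 (microglia-like) and 27.0 (oligodendrocyte-like). Between the sides it turned endothelial activation and Vcam1 to -0.025 at day 7, and Tnf to -0.099 and cytokines to -0.06 in microglia-like cells at day 14. Day 14 to day 7, it turned Ackr1 to 0.86 and 2.79, and contralaterally Lrg1 to 1.10 and Ptgs2 to 0.59. In microglia-like cells it turned disease-associated genes to -0.15 and -0.081, and contralaterally interferon to 0.59, immediate early genes to -0.27 and Lpl to -0.76. In astrocyte-like cells immediate early genes turned to 0.11 ipsilaterally. Clusters differed much between the days, so this setting compares other cells than the class as a whole. In endothelial-like cells cluster 15 was kept contralaterally (24 cells at day 14) but not ipsilaterally (11 cells), so the sides used different clusters. Gene-length centring gave -0.13 and -0.13 (astrocyte homeostatic, day 7 and 14), -0.11 (pan-reactive, day 7), -0.024 (microglia homeostatic, day 14), 0.013 and -0.005 (blood-brain barrier), and 36.8%, 37.9%, 35.7% and 34.3% in the class order above, and turned Slc6a11 to -0.093 at day 7 and microglial Tnf to -0.028 at day 14.

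Relative to other classes, disease-associated and interferon medians at day 7 were 0.47 and 0.46, over only those members also expressed in other classes. The percent was 41.0 in astrocyte-like cells and crossed 50 in the others, at 50.4, 52.7 and 50.8. This setting removes what the classes share and also keeps fewer genes. It also turned mitochondrial genes to -0.031 and 0.17 in astrocyte-like cells (day 7 and 14) and 0.071 in microglia-like cells (day 14). Others were microglial Isg15 at 0.24 (day 14), ependymal Hspa1b at 0.14 (day 7) and endothelial immediate early genes at 0.005 (day 14). Day 14 to day 7, Per1 turned to 0.087 and 0.18 and immediate early genes to 0.12 ipsilaterally in astrocyte-like cells, and disease-associated genes to -0.087 ipsilaterally in microglia-like cells. Members well expressed in the class gave 0.12 (pan-reactive, day 14), 0.023 (disease-associated, day 7), 0.58 (interferon, day 7), and -2.85 and -3.31 (endothelial activation, ipsilateral and contralateral).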

Other observations

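The tests on equal cluster makeup and on endothelial-like and astrocyte-like cells (interferon genes) and on immediate early genes and batch (day 14 against day 7) were chosen only after the results were seen, as were the genes of mural-like and ependymal-like cells. Among genes higher at both days in mural-like cells, log2 ratios were 1.5 and 0.46 for the smooth muscle gene Tagln, 1.98 and 0.58 for the actin-associated gene Palld and 1.13 and 0.69 for Csrp1, which had -0.022 at day 14 in thinned cells. The matrix proteoglycan gene Dcn had -0.68 and -0.60. Palld had 22 contralateral counts at day 7. Cluster 33 held 7.27% of ipsilateral and 3.06% of contralateral mural-like cells at day 7, and 5.88% and 8.14% at day 14. A different mix of clusters stays open as a contribution to the mural-like values. The share of cluster 33, however, ran opposite ways at the days, while Tagln, Palld and Csrp1 were higher ipsilaterally at both. In ependymal-like cells the heat shock gene Hspa1b had -1.12 (0.14 relative to other classes) and -0.73, the matrix gene Cyr61 -0.73 and -0.47, and the glycosylation enzyme gene B4galt3 0.88 (-0.72 in thinned cells) and 0.59. The thinned values of Csrp1 and B4galt3 had no count minimum. Before thinning, B4galt3 had 54 ipsilateral and 59 contralateral counts at day 7.

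Interferon-induced genes were higher on the injured side in microglia-like cells at both days. A difference between libraries shared by all classes was argued against as the whole cause at day 7, since the median in endothelial-like cells was -0.11, and stays open at day 14, with 0.11 in endothelial-like and 0.38 in astrocyte-like cells. The day 7 microglial median relative to other classes was smaller but still above 0. That setting keeps only members also expressed in other classes, so its smaller value cannot be read as the removal of a shared part. A shared part stays open at day 7. A different mix of clusters was argued against as the whole cause, since the smaller median with equal cluster makeup was 0.39. Without cells holding a UMI of a blood or border immune marker the median was 0.65 at day 7 (9 of 9 measured members higher, 638 against 517 cells), which argues against such cells as the whole cause there. At day 14 it was 0.13 (8 of 12 higher, 2065 against 1731 cells), above the 0.092 SD of random lists but far below 0.44, so a contribution of such cells or their free RNA stays open, as does an injury response with 1 library per side.

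The genes with the lowest ratios of day 14 to day 7 on both sides included Sgk1 and Plin4 in oligodendrocyte-like and Lcn2 and Ackr1 in endothelial-like cells, but with equal cluster makeup Ackr1 turned to 0.86 and 2.79 and the contralateral endothelial activation median to 0.52. A longer or harsher dissociation of the day 7 tissue is a candidate explanation, since immediate early genes had medians of -0.74 and -1.11 in oligodendrocyte-like and -0.88 and -0.7 in endothelial-like cells, against 0.39 and 0.2 in microglia-like cells. With equal cluster makeup 3 of the first 4 lay inside the range of matched lists (-0.15 in oligodendrocyte-like, -0.11 and -0.10 in endothelial-like cells) and the contralateral microglial value turned to -0.27. Clusters were made on all libraries together and differed much between the days, so holding them equal can remove a difference between the days itself. In endothelial-like cells that setting also kept cluster 15 on the contralateral side only. Equal cluster makeup therefore cannot decide between these explanations. A glucocorticoid response at day 7 is another candidate. A list of 14 glucocorticoid targets left out Sgk1, Plin4, Klf15 and Zbtb16. Its medians were -1.47 and -1.64 in oligodendrocyte-like and -0.96 and -0.92 in endothelial-like cells, all below 95% of matched lists. They were -0.39 and -0.56 in astrocyte-like and -0.51 and -0.51 in microglia-like cells, where the ipsilateral values lay inside that range. The list kept genes that were as low in oligodendrocyte-like cells, among them Sult1a1 (-4.53 and -5.93) and Fkbp5 (-3.20 and -2.87). It is therefore not independent of the pattern. Of the days, 0 had more than 1 pair of libraries, so a difference between library batches cannot be told apart from time after injury.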
